A study of Mus musculus with 9 samples.

How the data were processed

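RNA sequencing was used to measure gene expression in major histocompatibility complex class II positive (MHCII+) myeloid cells sorted from the peritoneal cavity of C57BL/6 mice aged 8 weeks. Per the labels, cDNA was made with a SMARTer Ultra Low RNA kit and sequenced on an Illumina NovaSeq. The submitters' processing notes name bcl2fastq 1.8.4, HISAT2 2.1.0, StringTie 1.3.4d and Cufflinks, with the mouse build mm10. The version and role of Cufflinks and any filter on genes are not given in the sources used here. The deposited table holds FPKM values, fragments scaled by transcript length and library size, for 24532 genes in 9 libraries. Of these genes 8597 are listed at 0 in every library. The authors call the values normalized, and what was done beyond FPKM is not stated. The FPKM totals differ between libraries. Gene coordinates were taken from the RefSeq annotation of GRCm38.p6, which has the same coordinates as mm10.

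The libraries fall into 5 groups, and the group of each library was taken from the labels. Small peritoneal macrophages (SPM), the P-IV.II subset, the P-IV.I subset and type 2 peritoneal dendritic cells (PcDC2) have 2 libraries each, and type 1 peritoneal dendritic cells (PcDC1) have 1. Read counts are not part of the table. Low values were searched for steps of 1 read, and 5.23% of 478 low genes shared the commonest ratio within 1%, so whole reads were not recoverable and the depth is unknown. No interval that needs a count is therefore given. Nothing in the sources used here says whether the 2 libraries of a group come from separate animals or separate sorts, so the p-values measure only the spread between these samples.

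FPKM values were transformed as log2(FPKM + 1). Genes with an FPKM of at least 1 in at least 2 libraries were tested, 10526 in all. Group means were fitted in R 4.3.3 with limma 3.58.1, using lmFit, contrasts.fit and eBayes with a trend of variance on mean expression, over all 9 libraries. The fit has 4 residual degrees of freedom, to which the empirical Bayes prior added 4.02. The 6 pairwise comparisons of the 4 replicated groups were tested, and p-values were adjusted by the Benjamini-Hochberg method within each comparison with a threshold of 0.05. A change is given as the log2 fold change ± its standard error (SE) from this fit, with 2 libraries per group, and every p-value is two-sided. The difference between P-IV.I minus P-IV.II and PcDC2 minus SPM was tested as an interaction contrast in the same fit. PcDC1 entered no test and is given as values of 1 library.

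Gene lists for cell types, pathways and receptor families were fixed before the data were examined, as were the comparisons, the threshold, the rule for named genes and the alternatives below. The 28 lists with at least 4 tested members were tested with camera in limma, at a preset correlation between genes of 0.01, and adjusted over the lists within each comparison. Every list was tested again with the correlation estimated from the data. For each list the member calls are given from the adjustment over all tested genes and adjusted over the list alone.

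Position between SPM and PcDC2 was computed over the genes with an adjusted p under 0.05 and an absolute log2 fold change of at least 1 between these 2 groups, by projecting each library on the line from the SPM mean (0) to the PcDC2 mean (1). Named genes follow a rule. It takes the genes of the sort gate and, per list, up to 4 members with an adjusted p under 0.05 and the largest absolute change. Where no member passes, it takes up to 2 members given as not passing. It adds the highest and lowest changes among genes without overlap between libraries and with a mean FPKM of at least 10 in the higher group, 6 each for P-IV.I minus P-IV.II and 4 each for the other comparisons. It also takes the genes higher in 1 P-IV subset than in each of the other replicated groups, and for PcDC1 up to 6 members of the type 1 dendritic cell list and the 4 highest and 4 lowest differences from PcDC2. Predicted genes, pseudogenes and antigen receptor segments are left out of the named genes.

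The fit was tested on simulated data of the same size. Of 100 genes changed by 1 on the log2 scale 32 were called, of 100 genes changed by 2 on that scale 95 were called, and of 9926 unchanged genes 22 were called. Simulated positions of 0.75 and 0.25 were returned as 0.748 and 0.252. The simulated errors were independent between genes and libraries, and the genes of the simulated position were known in advance. The simulation therefore does not measure errors from effects shared within a library, or from choosing position genes on the same libraries.

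The alternatives tried were pseudocounts of 0.1 and 5, a gene filter of a value above 0 or of FPKM of at least 5 in 2 libraries, median-ratio rescaling, quantile normalization, no variance trend, library weights, a fit on only the groups compared, a test against a log2 fold change of 1 (treat), a block on the replicate number, leaving out PcDC1, and leaving out each other library in turn. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.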

Results

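The data are FPKM values for MHCII+ cells of the mouse peritoneal cavity, sorted by CD11c, an integrin of dendritic cells and some macrophages encoded by Itgax, and by CD115, the receptor for macrophage colony-stimulating factor encoded by Csf1r. SPM are labelled small peritoneal macrophages and were sorted as CD11c- CD115+ cells. P-IV.II and P-IV.I both lie in the CD11c+ CD115+ gate, where the labels call P-IV.II small peritoneal macrophages and P-IV.I peritoneal dendritic cells. PcDC2 and PcDC1 are the type 2 and type 1 dendritic cells of the CD11c+ CD115- gate. There were 2 libraries for each group except PcDC1, which had 1. FPKM totals ranged from 439597 in P-IV.I replicate 2 to 647385 in PcDC1, and between 9115 and 9847 genes per library reached an FPKM of 1. Read depth is unknown. Pearson's r between the 2 libraries of a group, across genes, lay between 0.950 and 0.973. It was as high between some libraries of different groups, at 0.961 for SPM replicate 1 with P-IV.II replicate 1 and at 0.962 and 0.965 for P-IV.I replicate 1 with the PcDC2 libraries.

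The sort markers separated the groups at the RNA level. Csf1r (Entrez 12978, chromosome 18, 61105572 to 61131139, mm10) had a mean FPKM of 608 ± 186 (SD, n = 2) in SPM, 310 ± 23.8 in P-IV.II, 201 ± 62.9 in P-IV.I and 5.97 ± 1.26 in PcDC2, and was listed at 0 in PcDC1. Itgax (Entrez 16411, chromosome 7, 128129526 to 128150657) had a mean FPKM of 2.16 ± 0.178 in SPM, 27.1 ± 6.96 in P-IV.II, 99.9 ± 7.14 in P-IV.I and 84.4 ± 9.37 in PcDC2, and 27.1 in PcDC1. Within the CD11c+ CD115+ gate Itgax was higher in P-IV.I by 1.86 ± 0.25 on the log2 scale (adjusted p = 0.0036), and Csf1r did not pass the test, with a log2 fold change of -0.65 ± 0.32 (adjusted p = 0.23). The MHC class II genes H2-Ab1 (chromosome 17, 34263227 to 34269418), H2-Aa (chromosome 17, 34282744 to 34287823) and H2-Eb1 (chromosome 17, 34305867 to 34316674) were among the abundant transcripts of every group, with mean FPKM from 3968 ± 1884 for H2-Eb1 in SPM to 18567 ± 1524 for H2-Ab1 in PcDC2. These 3 genes passed in none of the 6 comparisons by limma on the deposited scale, but quantile normalization changed this. Under it H2-Aa and H2-Ab1 passed in P-IV.I minus P-IV.II and in PcDC2 minus SPM, P-IV.I minus SPM and P-IV.II minus PcDC2, and H2-Eb1 passed in PcDC2 minus SPM.

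**Figure D1:**
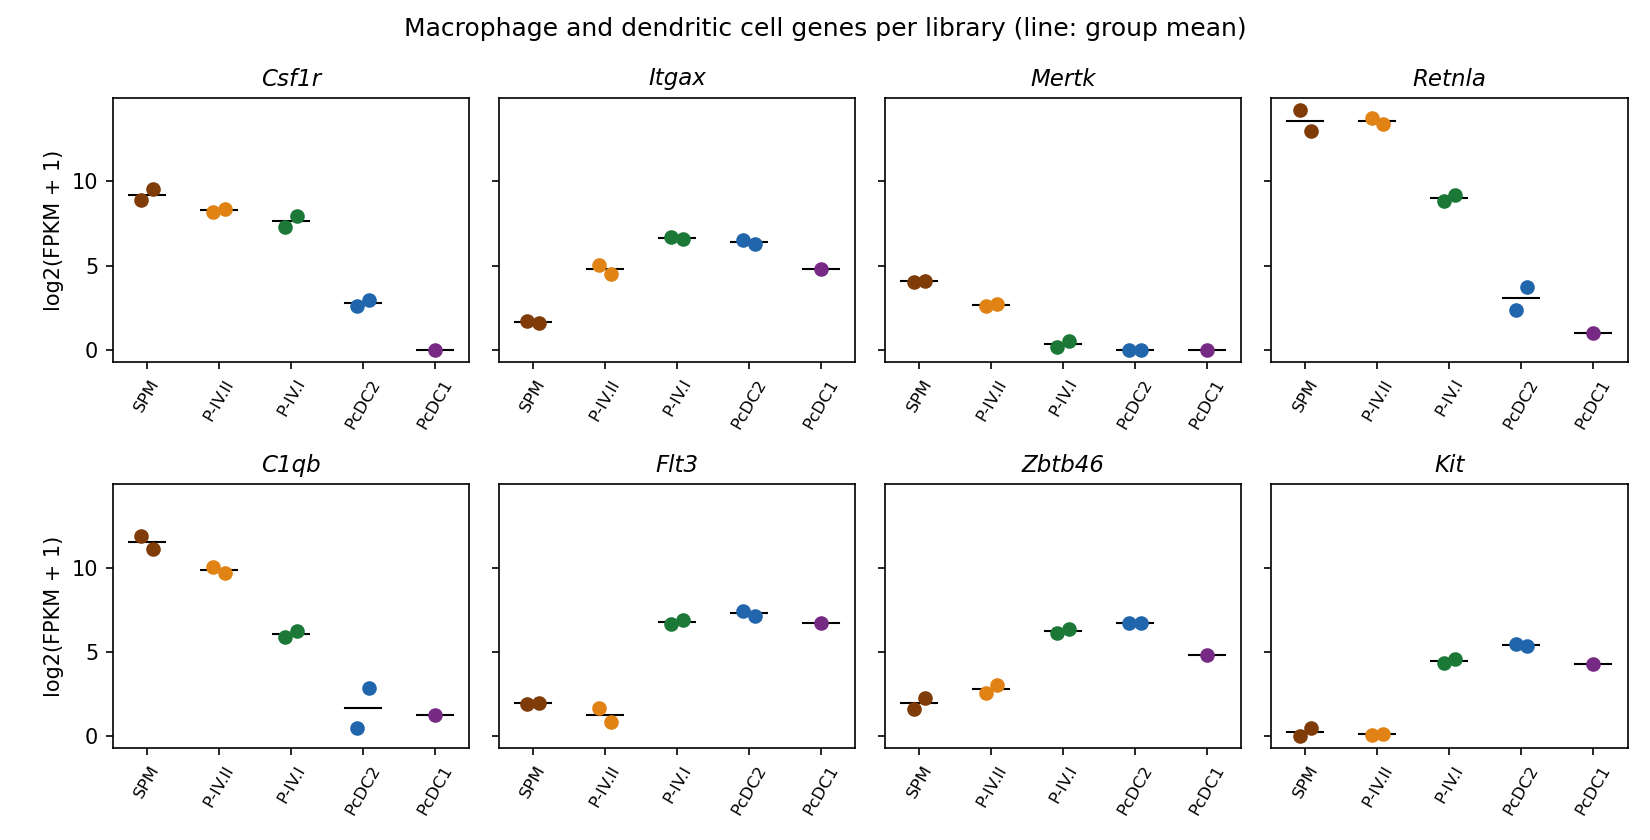
Expression of 8 marker genes as log2(FPKM + 1) on the vertical axis, 1 point per library, for SPM, P-IV.II, P-IV.I, PcDC2 and PcDC1, with a line at each group mean. Flt3 and Kit are near 0 to 2 in SPM and P-IV.II and above 4 in P-IV.I and PcDC2, while Csf1r is high in the first 3 groups and low in PcDC2.

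The comparison of P-IV.I with P-IV.II asks how the dendritic cell and the macrophage subset of the same CD11c+ CD115+ gate differ. Several genes of the dendritic cell lineage were higher in P-IV.I. Flt3, the receptor for the growth factor that drives dendritic cell development, was at 2.23 and 0.765 FPKM in the P-IV.II libraries and at 110 ± 11.7 in P-IV.I, a log2 fold change of 5.54 ± 0.31 (adjusted p = 0.00036). Zbtb46, a transcription factor of conventional dendritic cells, was higher by 3.43 ± 0.30 (adjusted p = 0.00097), and Kit, the stem cell factor receptor, by 4.34 ± 0.26 (adjusted p = 0.00036). Of the 19 tested genes of the conventional dendritic cell core list 12 were higher, 0 were lower and 7 did not pass, and adjusted over the list alone 13 were higher. The list was called higher by camera (adjusted p = 1.3e-08), and that call was lost with an adjusted p = 0.157 with an estimated correlation.

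Several macrophage genes were lower in P-IV.I than in P-IV.II. Retnla, an alternative activation gene of cavity macrophages, was at 12279 ± 1838 FPKM in P-IV.II and 521 ± 82.1 in P-IV.I, a log2 fold change of -4.56 ± 0.52 (adjusted p = 0.0022). Lyz1, a lysozyme, changed by -4.75 ± 0.35 (adjusted p = 0.00050), the complement gene C1qc by -3.85 ± 0.48 (adjusted p = 0.0029), the low-affinity Fc receptor Fcgr3 by -2.52 ± 0.24 (adjusted p = 0.0014) and Mertk, a receptor for apoptotic cells, by -2.35 ± 0.22 (adjusted p = 0.0014). The macrophage core list had 12 members lower, 2 higher and 12 not passing of 26 tested, with 16 lower and 2 higher adjusted over the list alone. Camera gave the macrophage core list an adjusted p = 1.4e-10, and adjusted p = 0.157 with an estimated correlation. The resident small cavity macrophage list had 5 lower, 1 higher and 10 not passing of 16, with 10 lower and 2 higher adjusted over the list alone. For the resident small cavity macrophage list camera gave an adjusted p = 4.1e-05, and adjusted p = 0.157 with an estimated correlation. When 1 library was left out, 6 to 12 macrophage core members were lower and 11 to 12 members of the dendritic cell core list were higher.

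Some members of further gene lists differed between P-IV.I and P-IV.II, in part of the lists only a few. Type 1 dendritic cell genes such as Xcr1, a chemokine receptor, at 2.89 ± 0.42 (adjusted p = 0.0054), and Cadm1, an adhesion molecule, at 2.37 ± 0.29 (adjusted p = 0.0026), were higher in P-IV.I. Of this list 10 were higher, 2 lower and 7 not passing of 19, with 12 higher and 3 lower adjusted over the list alone. Camera gave the type 1 dendritic cell list an adjusted p = 0.0019, and adjusted p = 0.452 with an estimated correlation. In the MHC class II pathway list 5 of 15 were higher, 0 lower and 10 did not pass (6 higher and 2 lower adjusted over the list alone), among them H2-Oa at 4.83 ± 0.32 (adjusted p = 0.00038) and H2-Ob at 2.80 ± 0.21 (adjusted p = 0.00053), which form a modulator of peptide loading, and Ciita, the master regulator of class II genes, at 1.66 ± 0.23 (adjusted p = 0.0041). That list as a whole was not called by camera on the deposited scale (adjusted p = 0.127, and adjusted p = 0.596 with an estimated correlation). After quantile normalization camera called it higher (adjusted p = 0.00017) at the preset correlation, and this call was not repeated with an estimated one. When 1 library was left out, 5 to 10 type 1 dendritic cell genes and 3 to 6 class II pathway genes were higher. Interferon-stimulated genes had 8 higher, 0 lower and 16 not passing of 24 (9 higher adjusted over the list alone; camera adjusted p = 0.0041, and adjusted p = 0.452 with an estimated correlation), with Ifit2 at 1.89 ± 0.24 (adjusted p = 0.0029). This list's call was lost without P-IV.II replicate 2 (adjusted p = 0.0944), and 1 to 7 members were higher when 1 library was left out. After median-ratio rescaling 4 of its members were higher, and after quantile normalization 3. The cell cycle list was called lower in P-IV.I at the preset correlation, with 3 lower, 0 higher and 23 not passing of 26 (4 lower adjusted over the list alone; camera adjusted p = 2.2e-06, and adjusted p = 0.452 with an estimated correlation); 0 to 4 members were lower when 1 library was left out. At the preset correlation the interferon-stimulated and cell cycle lists were called in every comparison with P-IV.II. Neither was called in PcDC2 minus SPM (camera adjusted p = 0.231 and 0.863). P-IV.II minus PcDC2 had 10 interferon-stimulated genes lower (camera adjusted p = 0.0133) and 9 cell cycle genes higher (6.5e-08). By camera the cell cycle list was higher in P-IV.I than in PcDC2 (0.00017) and SPM (0.0412). None remained with an estimated correlation. Immediate early and stress genes, which also respond to cell handling, took 3.93% and 4.47% of the FPKM total in the P-IV.I libraries and 2.85% and 1.53% in the P-IV.II libraries. Of these 2 were higher, 0 lower and 20 not passing of 22, with 0 passing adjusted over the list alone. For the immediate early and stress response list camera gave an adjusted p = 0.025, and adjusted p = 0.596 with an estimated correlation. Without P-IV.II replicate 2 the adjusted p of this list was 0.233, and without P-IV.I replicate 1 it was 0.0685. Its members called higher then numbered 0 to 3 over the left-out libraries, 0 after median-ratio rescaling and 1 after quantile normalization.

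Some markers of another cell type, the plasmacytoid dendritic cell, were higher in P-IV.I than in P-IV.II and in PcDC2 than in SPM. In P-IV.I minus P-IV.II 5 were higher, 0 lower and 4 not passing of 9 (5 higher adjusted over the list alone; camera adjusted p = 0.0196, and adjusted p = 0.452 with an estimated correlation), among them Tcf4, a transcription factor, at 1.86 ± 0.23 (adjusted p = 0.0029). That call was lost without P-IV.II replicate 2 (adjusted p = 0.0569), and 1 to 5 members were higher when 1 library was left out. In PcDC2 minus SPM 6 were higher, 0 lower and 3 not passing of 9 (7 higher adjusted over the list alone; camera adjusted p = 0.00095, and adjusted p = 0.235 with an estimated correlation).

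Across all genes, 685 were higher and 327 lower in P-IV.I than in P-IV.II, 1012 of 10526. The median log2 fold change of all tested genes was 0.19, and the division into higher and lower moved with it: after median-ratio rescaling, which brought the median to -0.01, 469 were higher and 518 lower, and after quantile normalization 454 were higher and 462 lower. Of the 1012 calls 796 remained after median-ratio rescaling. The total fell to 599 without P-IV.II replicate 1, 368 without P-IV.II replicate 2, 366 without P-IV.I replicate 1 and 530 without P-IV.I replicate 2.

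The comparison of PcDC2 with SPM sets the dendritic cell and the macrophage outside the CD11c+ CD115+ gate against each other. Several macrophage transcripts were at low levels in PcDC2: Retnla went from 13575 ± 7954 FPKM in SPM to 8.32 ± 5.70 in PcDC2 (log2 fold change -10.52 ± 0.52, adjusted p = 1.9e-05) and C1qb from 2994 ± 1065 to 3.37 ± 4.20 (-9.82 ± 0.67, adjusted p = 6.2e-05). Mertk was at 15.7 and 16.0 FPKM in the SPM libraries and listed at 0 in both PcDC2 libraries. Several dendritic cell genes were higher, with Flt3 at 5.33 ± 0.31 (adjusted p = 3.0e-05), Zbtb46 at 4.77 ± 0.30 (adjusted p = 4.1e-05) and Ccr7, the chemokine receptor that guides cells to lymph nodes, at 5.76 ± 0.72 (adjusted p = 0.00096). The macrophage core list had 23 members lower, 1 higher and 2 not passing of 26, with 23 lower and 1 higher adjusted over the list alone. For the macrophage core list camera gave an adjusted p = 1.25e-21, and adjusted p = 0.0474 with an estimated correlation. The resident small cavity macrophage list had 12 lower, 1 higher and 3 not passing of 16, with 12 lower and 1 higher adjusted over the list alone. For the resident small cavity macrophage list camera gave an adjusted p = 2.2e-10, and adjusted p = 0.0474 with an estimated correlation. The lipid efflux and storage list, with Lpl, the lipoprotein lipase, at -5.76 ± 0.26 (adjusted p = 1.7e-05), had 8 lower, 1 higher and 9 not passing of 18, with 11 lower and 1 higher adjusted over the list alone. For the lipid efflux and storage list camera gave an adjusted p = 1.05e-06, and adjusted p = 0.0474 with an estimated correlation. The conventional dendritic cell core list had 13 higher, 0 lower and 6 not passing of 19, with 17 higher adjusted over the list alone. For the conventional dendritic cell core list camera gave an adjusted p = 4.1e-11, and adjusted p = 0.0827 with an estimated correlation. The migratory and mature dendritic cell list had 15 higher, 0 lower and 8 not passing of 23, with 18 higher and 2 lower adjusted over the list alone. For the migratory and mature dendritic cell list camera gave an adjusted p = 2.4e-07, and adjusted p = 0.235 with an estimated correlation.

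In all, 1178 genes were higher and 891 lower in PcDC2 than in SPM, 2069 of 10526. The median of all genes was 0.13, and the division became 963 higher and 1089 lower after median-ratio rescaling (median -0.02). Immediate early and stress genes took 4.49% and 3.30% of the FPKM total in the PcDC2 libraries and 1.27% and 0.678% in the SPM libraries, and 15 of the 22 were higher, 0 lower and 7 not passing (19 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.3e-05, and adjusted p = 0.251 with an estimated correlation), a count of 2 to 16 when 1 library was left out. After median-ratio rescaling 11 of them were higher and 1 lower. The total of 2069 fell to 1359 without SPM replicate 2, 1265 without PcDC2 replicate 1 and 1089 without PcDC2 replicate 2.

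Most genes called in P-IV.I minus P-IV.II changed the same way in PcDC2 minus SPM, which had more calls in all (2069 against 1012). Of the 814 genes called in both P-IV.I minus P-IV.II and PcDC2 minus SPM, 810 (99.5%) changed the same way, 530 higher and 280 lower. Had the calls been independent, 76.7 would have been higher in both and 27.7 lower in both. Across genes, which are not independent replicates, Pearson's r between the 2 sets of log2 fold changes was 0.76 and Spearman's rho 0.67. On the line from SPM (0) to PcDC2 (1), over 1787 genes, the mean position was 0.188 ± 0.0752 (SD, n = 2) for P-IV.II and 0.707 ± 0.0495 for P-IV.I, and the spread within SPM was 0.0310 (SD). P-IV.I stood at 0.786 ± 0.0268 on the genes higher in PcDC2 and at 0.637 ± 0.0695 on the genes higher in SPM. P-IV.II stood at 0.151 ± 0.149 and 0.220 ± 0.0104 on these 2 sets of genes, and the order differed between its libraries. Replicate 1 stood at 0.256 and 0.228, and replicate 2 at 0.0455 and 0.213. The single PcDC1 library stood at 0.811 over all these genes, at 0.517 on the genes higher in PcDC2 and at 1.07 on the genes higher in SPM.

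**Figure D2:**
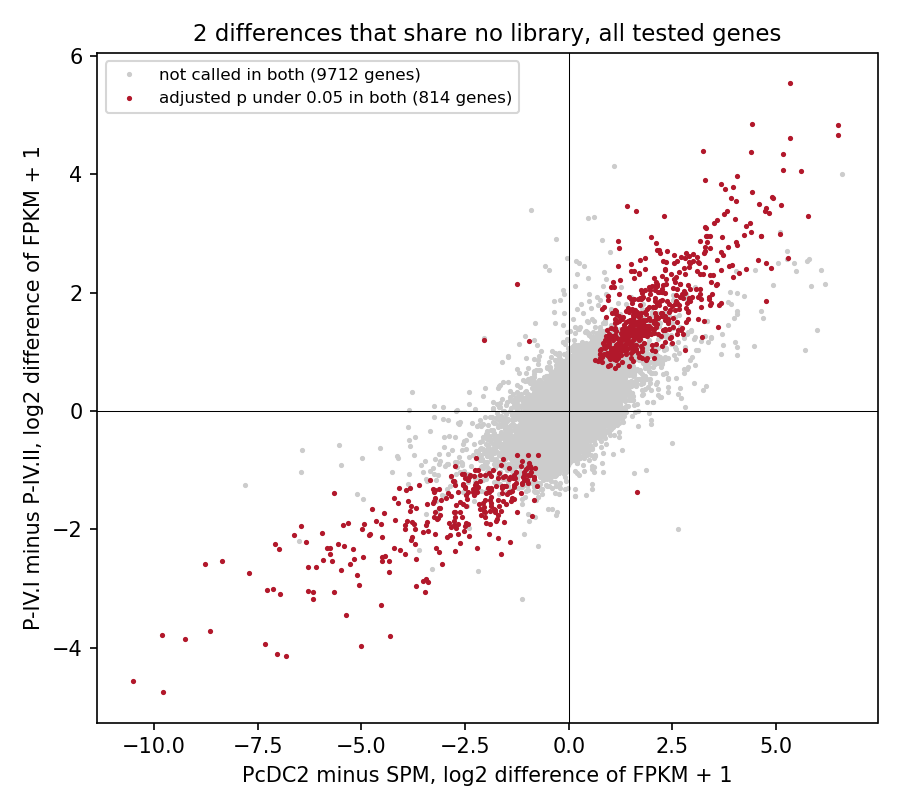
Each point is 1 tested gene, with the log2 fold change of PcDC2 minus SPM on the horizontal axis and of P-IV.I minus P-IV.II on the vertical axis; red points have an adjusted p under 0.05 in both. Of the 814 red genes, 810 lie in the quadrants of equal sign.

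**Figure D3:**
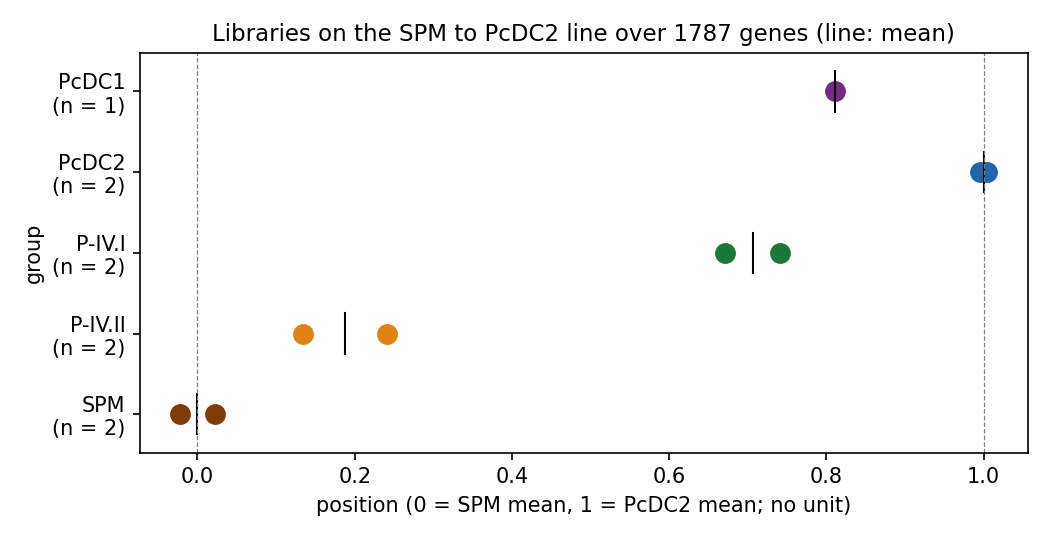
Position of each library between the SPM mean (0) and the PcDC2 mean (1) over 1787 genes, 1 point per library, with a line at each group mean. P-IV.II lies at 0.241 and 0.135, and P-IV.I at 0.742 and 0.672.

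The comparison of P-IV.II with SPM asks what sets the CD11c+ macrophage subset apart from the CD11c- one. P-IV.II had less of several genes of tissue-resident macrophages. Folr2, a folate receptor, was at 112 ± 35.6 FPKM in SPM and 4.57 ± 0.208 in P-IV.II (log2 fold change -4.30 ± 0.28, adjusted p = 0.00073), Lyve1, a hyaluronan receptor, at 19.8 ± 3.78 and 0.196 ± 0.110 (-4.11 ± 0.23, adjusted p = 0.00053), and Timd4, a phosphatidylserine receptor, at 22.5 ± 0.781 and 1.99 ± 0.0209 (-2.98 ± 0.24, adjusted p = 0.0014). The C-type lectin Cd209f changed by -3.34 ± 0.22 (adjusted p = 0.00073), the scavenger receptor Msr1 by -4.26 ± 0.33 (adjusted p = 0.0014) and Lrg1 by -4.38 ± 0.29 (adjusted p = 0.00073). Itgax, which encodes the marker that parts the 2 sorts, was higher by 3.13 ± 0.25 (adjusted p = 0.0014). The macrophage core list had 5 lower, 0 higher and 21 not passing of 26, with 16 lower adjusted over the list alone. For the macrophage core list camera gave an adjusted p = 1.2e-09, and adjusted p = 0.192 with an estimated correlation. The scavenger and clearance receptor list had 4 lower, 0 higher and 13 not passing of 17, with 6 lower adjusted over the list alone. For the scavenger and clearance receptor list camera gave an adjusted p = 2.3e-07, and adjusted p = 0.192 with an estimated correlation. In the resident small cavity macrophage list 3 were lower, 0 higher and 13 not passing of 16 (3 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.0085, and adjusted p = 0.192 with an estimated correlation), and this call was lost without SPM replicate 1 (adjusted p = 0.0672). Of the macrophage core list 0 to 3 members were lower when 1 library was left out.

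Marker lists of other myeloid cells were called lower in P-IV.II than in SPM as well, at the preset correlation. The large peritoneal macrophage list had 3 lower, 0 higher and 17 not passing of 20 (6 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00065, and adjusted p = 0.27 with an estimated correlation), and its genes took 0.259% and 0.182% of the FPKM total in SPM and 0.176% and 0.0851% in P-IV.II. The monocyte list had 4 lower, 0 higher and 17 not passing of 21 (9 lower and 2 higher adjusted over the list alone; camera adjusted p = 4.3e-05, and adjusted p = 0.192 with an estimated correlation). When 1 library was left out, 1 to 2 large peritoneal macrophage genes and 0 to 2 monocyte genes were lower. The neutrophil list had only 2 tested members and entered no list test. Its genes, of which Mmp9 was the most abundant, summed to 137 and 191 FPKM in SPM and to 13.9 and 11.4 in P-IV.II. In PcDC2 the sums were 2.07 and 1.24 FPKM. Whether they come from other cells in the sorts was not tested.

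As lists, interferon-stimulated genes were called lower and cell cycle genes higher in P-IV.II than in SPM at the preset correlation, though few members passed. Of 24 interferon-stimulated genes 4 were lower, 0 higher and 20 did not pass (15 lower adjusted over the list alone; camera adjusted p = 3.5e-09, and adjusted p = 0.192 with an estimated correlation), and of 26 cell cycle genes 2 were higher, 0 lower and 24 did not pass, with 13 higher adjusted over the list alone. For the cell cycle list camera gave an adjusted p = 5.3e-18, and adjusted p = 0.192 with an estimated correlation. The 2 cell cycle calls were Cdk1, the mitotic kinase, at 1.52 ± 0.22 (adjusted p = 0.025) and Stmn1, a microtubule regulator, at 2.07 ± 0.29 (adjusted p = 0.020). Cdk1 lost its call without any 1 of the 8 libraries of the replicated groups, with an adjusted p of up to 0.157 without SPM replicate 2. Stmn1 lost it without each library of SPM, P-IV.II and PcDC2, with an adjusted p of up to 0.108 without SPM replicate 2. Either 0 or 1 cell cycle gene was then higher, while 4 were higher after median-ratio rescaling and 3 after quantile normalization. Of the interferon-stimulated genes 0 to 2 were lower when 1 library was left out. Immediate early and stress genes took 2.85% and 1.53% of the FPKM total in P-IV.II and 1.27% and 0.678% in SPM; by limma 0 of the 22 passed, on the full adjustment and adjusted over the list alone, and the list was called higher (camera adjusted p = 1.9e-08, and adjusted p = 0.192 with an estimated correlation).

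Fewer genes separated these macrophage subsets than the subsets of the CD11c+ CD115+ gate: 25 were higher and 95 lower in P-IV.II, 120 of 10526, and 1155 had an unadjusted p under 0.05. The count was 50 without SPM replicate 1, 44 without SPM replicate 2, 24 without P-IV.II replicate 1, 55 without P-IV.II replicate 2, 62 without P-IV.I replicate 1, 63 without P-IV.I replicate 2, and 44 without either PcDC2 replicate 1 or PcDC2 replicate 2. Without PcDC1 it was 124, with all 120 kept. P-IV.I and PcDC2 libraries are not compared here. Leaving 1 of them out keeps every log2 fold change and alters only the shared estimate of spread and its degrees of freedom. Those drops are therefore not changes in P-IV.II or SPM. The excess of lower genes also depends on the libraries: without P-IV.II replicate 2 there were 27 higher and 28 lower, without P-IV.II replicate 1 there were 2 and 22, and without SPM replicate 2 or either PcDC2 library 3 and 41. A fit on only these 2 groups called 7. That last fit kept Folr2, Lyve1 and Lrg1 but not Msr1, Timd4, Cd209f or Itgax.

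The comparison of P-IV.I with PcDC2 sets the CD115+ dendritic cell subset against the CD115- one. Csf1r was higher by 4.83 ± 0.32 (adjusted p = 0.00066), as the sort by CD115 would give. The P-IV.I libraries also held some macrophage-associated transcripts that PcDC2 had at far lower levels. For Lyz1 and Retnla a small share of P-IV.II cells in the sort cannot be told apart from expression in P-IV.I. Lyz1 was higher by 5.35 ± 0.35 (adjusted p = 0.00066), Retnla by 5.95 ± 0.52 (adjusted p = 0.0024), Fcgr3 by 3.38 ± 0.24 (adjusted p = 0.00087), Lpl by 3.96 ± 0.26 (adjusted p = 0.00066) and Tgfbi, a matrix protein, by 3.83 ± 0.27 (adjusted p = 0.00078). Fcrls, an Fc receptor-like gene, was at 265 ± 104 FPKM in P-IV.I and 4.85 ± 0.552 in PcDC2 (5.45 ± 0.32, adjusted p = 0.00066). The macrophage core list had 8 members higher, 0 lower and 18 not passing of 26 (14 higher and 1 lower adjusted over the list alone; camera adjusted p = 3.4e-19, and adjusted p = 0.0645 with an estimated correlation), and 1 to 5 were higher when 1 library was left out. In the resident small cavity macrophage list 3 were higher, 0 lower and 13 not passing of 16, with 7 higher adjusted over the list alone. For the resident small cavity macrophage list camera gave an adjusted p = 2.7e-09, and adjusted p = 0.0645 with an estimated correlation. Of the lipid efflux and storage list 3 were higher, 0 lower and 15 not passing of 18 (4 higher adjusted over the list alone; camera adjusted p = 8.9e-06, and adjusted p = 0.0645 with an estimated correlation), and 1 to 2 were higher when 1 library was left out.

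Few single dendritic cell genes passed between P-IV.I and PcDC2, while several of their lists were called. By limma 0 of the 19 genes of the conventional dendritic cell core list passed, over all genes and adjusted over the list alone, and the list as a whole was called lower in P-IV.I (camera adjusted p = 8.9e-06, and adjusted p = 0.125 with an estimated correlation). The migratory and mature dendritic cell list was also called lower. It had 1 lower, 0 higher and 22 not passing of 23, with 6 lower adjusted over the list alone. For the migratory and mature dendritic cell list camera gave an adjusted p = 5.1e-12, and adjusted p = 0.125 with an estimated correlation. The 1 call was Cacnb3, a calcium channel subunit, at -2.60 ± 0.31 (adjusted p = 0.011), which was lost without P-IV.I replicate 1 (adjusted p = 0.0679), P-IV.I replicate 2 (adjusted p = 0.0689) or PcDC2 replicate 2 (adjusted p = 0.0546). Of the 19 type 1 dendritic cell genes 0 passed by limma over all genes, 8 were higher adjusted over the list alone, and the list was called higher (camera adjusted p = 2.0e-09, and adjusted p = 0.125 with an estimated correlation). In total 63 genes were higher and 14 lower in P-IV.I, 77 of 10526, with 738 at an unadjusted p under 0.05. The count fell to 50 without SPM replicate 1 or SPM replicate 2, 47 (45 higher, 2 lower) without P-IV.I replicate 1 and 18 (17 higher, 1 lower) without P-IV.I replicate 2. It was 24 without PcDC2 replicate 1 and 15 (15 higher, 0 lower) without PcDC2 replicate 2.

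The remaining comparisons set each P-IV subset against the group of the other cell type outside its gate. P-IV.I against SPM gave 675 genes higher and 482 lower (520 and 630 after median-ratio rescaling, where the median of all genes went from 0.12 to -0.05), and the macrophage core list had 19 lower, 0 higher and 7 not passing of 26, with 22 lower adjusted over the list alone. For the macrophage core list camera gave an adjusted p = 5.2e-22, and adjusted p = 0.0661 with an estimated correlation. Cd209a, a C-type lectin, was higher in P-IV.I than in SPM by 2.77 ± 0.24 (adjusted p = 0.00051). It is a member of the type 2 dendritic cell list and also of the resident small cavity macrophage list. The type 2 dendritic cell list had 9 higher, 0 lower and 11 not passing of 20, with 11 higher and 2 lower adjusted over the list alone. For the type 2 dendritic cell list camera gave an adjusted p = 0.00016, and adjusted p = 0.318 with an estimated correlation. Quantile normalization gave 537 higher and 589 lower for P-IV.I against SPM. Of 22 immediate early and stress genes, which also respond to cell handling, 10 were higher, 0 lower and 12 not passing in P-IV.I. Camera gave that list an adjusted p = 1.6e-07, and adjusted p = 0.277 with an estimated correlation. The large peritoneal macrophage list had 8 lower, 1 higher and 11 not passing of 20. The plasmacytoid dendritic cell list had 5 higher, 0 lower and 4 not passing of 9. Of the type 2 dendritic cell list 5 to 8 members were higher when 1 library was left out. The total of 1157 was 764 without SPM replicate 1, 695 without SPM replicate 2, 554 without P-IV.I replicate 1 and 743 without P-IV.I replicate 2. P-IV.II against PcDC2 gave 792 higher and 1391 lower (1065 and 1018 after median-ratio rescaling, where the median went from -0.17 to 0.01), with Retnla at 10.51 ± 0.52 (adjusted p = 2.3e-05), Fcrls at 8.19 ± 0.32 (adjusted p = 1.7e-05) and Flt3 at -6.04 ± 0.31 (adjusted p = 2.7e-05). In this comparison the glycolysis list was called higher in P-IV.II, with 7 higher, 1 lower and 9 not passing of 17 (9 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.2e-05, and adjusted p = 0.0767 with an estimated correlation), including the monocarboxylate transporter Slc16a3 at 3.22 ± 0.39 (adjusted p = 0.0010). Quantile normalization gave 948 higher and 976 lower for P-IV.II against PcDC2. The total of 2183 was 1066 without P-IV.II replicate 2, 1146 without PcDC2 replicate 1 and 924 without PcDC2 replicate 2.

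**Figure D4:**
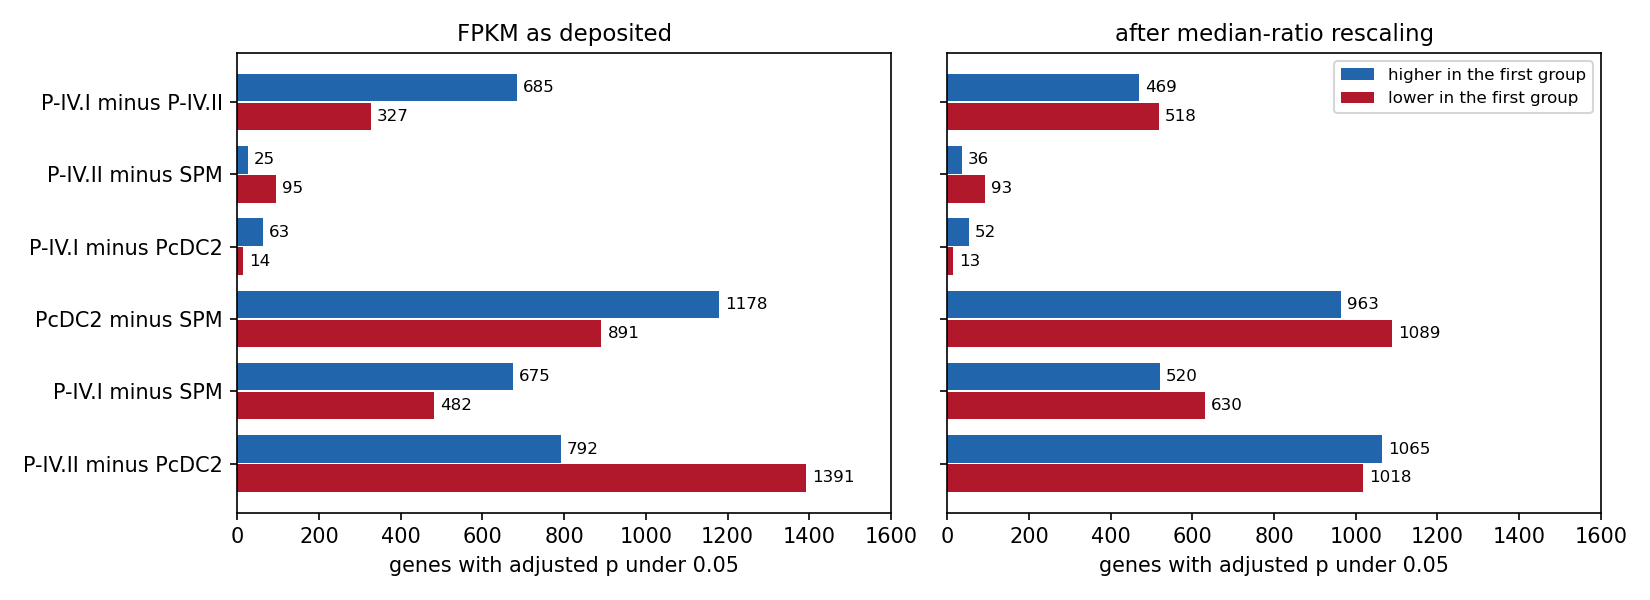
Number of genes with an adjusted p under 0.05, higher and lower, in the 6 comparisons, as bars for the deposited FPKM and after median-ratio rescaling. P-IV.I minus P-IV.II has 685 higher and 327 lower as deposited and 469 and 518 after rescaling, and P-IV.I minus PcDC2 has 63 and 14, then 52 and 13.

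Few genes were higher in 1 P-IV subset than in each of the other replicated groups. For P-IV.I there were 2: Treml4, a receptor of the triggering receptor family, at 13.8 ± 0.263 FPKM, and Ttc39a at 1.98 ± 0.463. Both were higher still in the PcDC1 library, at 106 and 14.8 FPKM. For P-IV.II there were 5: Cdk1 at a mean of 5.25 FPKM, F2rl2, a protease-activated receptor, at 26.2, Upb1, an enzyme of pyrimidine breakdown, at 38.1, Ldlrad1 at 1.62, and the unnamed gene 9830107B12Rik, at 3.17 and 5.69 FPKM in the P-IV.II libraries and listed at 0 in both PcDC2 libraries. This last gene lies outside the rule for named genes and was chosen after its values were seen. The P-IV.I count of 2 was 0 without SPM replicate 1, P-IV.I replicate 2 or PcDC2 replicate 2, 1 without SPM replicate 2, either P-IV.II library or PcDC2 replicate 1, and 3 without P-IV.I replicate 1. The P-IV.II count of 5 was 4 without SPM replicate 1, 1 without SPM replicate 2 or P-IV.I replicate 1, 3 without P-IV.II replicate 2, and 0 without P-IV.II replicate 1, P-IV.I replicate 2 or either PcDC2 library.

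PcDC1, the type 1 dendritic cells, are 1 library and were not tested. Against the PcDC2 libraries Xcr1 was at 131 FPKM in PcDC1 and 1.45 ± 1.41 in PcDC2, a log2 difference of 5.89. Irf8, a transcription factor that type 1 dendritic cells depend on, was at 1365 FPKM, and the tetraspanin Cd81 at 842, a log2 difference of 5.77. Sirpa, a receptor of type 2 dendritic cells and macrophages, was at 0.329 FPKM, a log2 difference of -6.98, and the lipid transfer gene Pltp at 2.41, a log2 difference of -7.00. Of the genes with an FPKM of at least 10 in either group, 2417 were higher and 2954 lower in PcDC1 than in both PcDC2 libraries. There is no replicate against which to set these differences. A value from 1 library often lies outside the range of 2 others without any true difference. How many genes were eligible is not given, so these counts do not show how many genes differ. The scale also differed, with a median FPKM of tested genes of 6.73 in PcDC1 and 9.56 and 9.75 in the PcDC2 libraries. Such a shift would by itself move genes towards lower in PcDC1.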

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

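The tests below of cells carried over from another gate, and of the scale behind the 63 genes, were chosen only after the results were seen. The test with P-IV.II cells was reworded after a first run, because that run used only genes selected for needing a high share, which is circular. The test of the scale replaced an earlier one, the 52 of the 63 genes still higher after median-ratio rescaling, because that rescaling moved little between these 2 groups (median of all genes from -0.01 to -0.03). The tests of the division into 685 and 327 were written before their own outcomes were seen. One of them, on 1 factor per library, replaced an earlier test that had come out as fitting such a factor.

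The change from macrophage to dendritic cell differed in size inside and outside the CD11c+ CD115+ gate for 117 genes. This is the count with an adjusted p under 0.05 for P-IV.I minus P-IV.II against PcDC2 minus SPM, and 101 of the 117 were called higher in SPM than in PcDC2. Values here are differences of log2 differences, and a positive one on a gene called higher in SPM means a smaller drop, or a rise, inside the gate. For 57 of the 101, among them F13a1, C1qa, C1qc, Folr2, Mmp9 and Ltc4s, the log2 level in P-IV.II was smaller than the drop outside the gate, so an equal drop was not possible. In 30 of these the gene had under 1 FPKM in P-IV.I, as did Folr2 (4.57 FPKM in P-IV.II and 0.201 in P-IV.I), Mmp9 (10.5 and 0.841) and Ltc4s (27.7 and 0.649), and the difference does not show expression kept by P-IV.I. The difference was 6.19 ± 0.67 (SE, adjusted p = 0.0075) for F13a1, 6.03 for C1qb, 5.97 for Retnla, 5.84 for Fn1, 5.77 ± 0.45 (adjusted p = 0.0061) for Csf1r (which encodes the sort marker CD115; of the 4 groups compared, PcDC2 alone was sorted as CD115-), 5.41 for C1qc, 5.04 for Lyz1 and 4.93 for C1qa. It was 4.52 for Cd36, 4.11 for Folr2, 3.46 for Mmp9, 3.44 for Lpl, 3.40 for Fcgr3, 3.09 for Lyz2, 2.68 for Ltc4s and 2.60 for Ctsd. Itgax, the gene of the sort marker CD11c, had -2.89, being at 2.16 FPKM in SPM and 27.1 in P-IV.II. Signs were opposite in 27 of the 117, and 4 of these were called in both differences. Cx3cr1 rose by 2.90 inside the gate and had -0.31 outside it (difference 3.21), and Timd4 had 1.98 and -0.10 (difference 2.08). The count of 117 was 61 and 60 without SPM replicate 1 and 2, 49 without P-IV.II replicate 1, 76 (59 higher, 17 lower, against 106 and 11) without P-IV.II replicate 2, 69 and 29 without P-IV.I replicate 1 and 2, and 44 and 39 without PcDC2 replicate 1 and 2.

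The 63 genes higher in P-IV.I than in PcDC2 could come from macrophages of the same gate carried into the sort. As the whole cause, P-IV.II cells would need a median of 20.6% of the P-IV.I libraries (17.1% and 24.2%). The 6 transcripts abundant in P-IV.II (C1qb, Ecm1, Fn1, Lyz1, Retnla and Fcrls) allow a median of 4.79% and 8.05% (highest 10.9% and 24.4%). All but Ecm1 are among the 63, which were chosen for being higher in P-IV.I, so these medians are not independent and do not decide it. The lowest values, 3.00% and 4.35%, are those of Lyz1, which a larger share of average P-IV.II cells would exceed. Of the 63 genes 57 needed more than 2 times these shares in both libraries, which argues against such cells as the whole cause. SPM cells, which the CD11c gate would remove, would need 20.1%, against 3.35% and 5.15% from 11 abundant transcripts. These transcripts include C1qb and Retnla, which are also among the 63, so the SPM medians are not independent and do not decide it either. The scale of the FPKM values would move all genes about as far as these 63 (median log2 fold change 2.56, lowest 1.35), but all tested genes had a median of -0.01 (5th to 95th percentile -0.57 to 0.66), which argues against it. For 6 genes (C1qb, C1qc, Lyz1, Sdc1, Retnla and Kazald1) a small share of P-IV.II cells and expression in P-IV.I itself cannot be told apart, because the true share of such cells in the P-IV.I libraries is not known. The other 57 are not all macrophage genes and include Csf1r, on whose product the cells were sorted; Treml4 had 2.40 FPKM in P-IV.II, 13.8 in P-IV.I and 106 in PcDC1, and their expression by P-IV.I cells is a hypothesis, not tested further.

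Type 1 dendritic cell genes higher in P-IV.I than in PcDC2, 8 adjusted over the list alone (Xcr1, Clec9a, Itgae, Cadm1, Tlr3, Naaa, Rab7b and Plpp1), could come from PcDC1 cells, which the CD115 gate would remove. The 8 genes would need a median of 3.82% and 6.34% PcDC1 cells in the 2 libraries. Naaa had 253 FPKM in SPM, 252 in P-IV.II and 247 in P-IV.I, and Rab7b had 40.6, 30.4 and 10.7. These 2 were therefore not particular to dendritic cells here. The 10 abundant PcDC1 transcripts outside the list, among them Cxcr3, Id1, Fcrla and P2ry14, give medians of 0.117% and 1.45%, a mean of 0.786%, and lowest values of -1.67% and -2.48%. The 8 list genes were chosen for being higher in P-IV.I than in PcDC2, which raises their share, and the 10 were not. The lower medians therefore do not decide against PcDC1 cells. Treml4 gives the highest value of the 10, 12.2% and 11.8%, and the PcDC1 profile rests on 1 library. A share of PcDC1 cells and a biological difference between the subsets both stay open, and the latter was not tested.

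More genes were higher (685) than lower (327) in P-IV.I than in P-IV.II, and the division was 47.5% higher after median-ratio rescaling and 49.6% after quantile normalization, against 67.7% as deposited. These values were the earlier test, set aside because both methods centre the genes and so nearly fix that outcome. A single factor per library would by itself shift genes of every level alike. The medians of expression bins, with libraries paired by replicate number, differed over a mean range of 0.324 (log2). They ran from 0.301 and 0.239 in the lowest bin to 0.0118 and -0.119 in the highest. A factor alone thus did not describe the shift at every level. Real changes related to level would also make the bins uneven, so a factor behind the excess is not excluded. The 119 genes among the top 50 of any library held 49.4% and 49.1% of the P-IV.II totals and 40.7% and 38.8% of the P-IV.I totals, yet the totals of the other genes were close (274712 and 267956 against 280102 and 268849 FPKM), so scaling to them could move little (67.1% of 1002 calls higher), and the near-equal totals argue against these transcripts as the whole cause. Transcript length cannot be told apart from the group: its Spearman correlation with the log2 fold change was 0.240 across 10234 genes. It was -0.278 for P-IV.II minus SPM and -0.176 for P-IV.II minus PcDC2. Without P-IV.II it was near 0, at 0.0166 for PcDC2 minus SPM and 0.0456 for P-IV.I minus SPM. Longer transcripts among dendritic cell genes would raise it in these 2 comparisons as well, which was not seen. For replicate 1 minus replicate 2 within a group it was -0.198 in SPM, -0.134 in P-IV.I, -0.0839 in P-IV.II and 0.0350 in PcDC2. Length bias in the libraries stays open, and neither explanation is settled.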

How the results depend on the processing

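Every alternative here was chosen before the data were examined; of the tests in this part, only the comparison of replicate deviations between groups was not among them and was added once the data were in hand. Of 192 values outside the leave-one-out runs, 149 stayed close (counts within a factor of 1.5) and 43 moved. The cause was not tested. Of 425 named calls, 413 were kept after median-ratio rescaling, 409 after quantile normalization, 391 and 409 with pseudocounts of 0.1 and 5, 360 with no filter, 359 with only the groups compared, 233 with treat, and 333 to 369 when 1 library was left out, and 0 reversed. Genes changed in P-IV.II minus SPM (120) were 53 with pseudocount 0.1, 71 with no filter, 77 with a filter of FPKM 5, 76 with library weights and 7 with only the groups compared. P-IV.I minus P-IV.II (1012) gave 650 and P-IV.I minus PcDC2 (77) gave 35 with only the groups compared, and the latter 126 with library weights. With treat against a log2 fold change of 1, P-IV.I minus P-IV.II kept 122, P-IV.II minus SPM 16, P-IV.I minus PcDC2 18, PcDC2 minus SPM 550, P-IV.I minus SPM 231, P-IV.II minus PcDC2 444 and the interaction 25, and the shared direction was 100% of 106 genes. Genes higher in P-IV.II than in each other group (5) were 0 with pseudocount 0.1, 10 with pseudocount 5, 2 with no filter, 2 with a filter of FPKM 5, 15 with median-ratio rescaling, 15 with quantile normalization, 3 with no mean-variance trend, 1 with library weights, 0 with only the groups compared and 0 with treat. For P-IV.I (2) the count was 1 with pseudocount 5, 5 with no filter, 1 with a filter of FPKM 5, 1 with quantile normalization, 1 with only the groups compared and 0 with treat. With an estimated inter-gene correlation, gene lists changed numbered 3 in PcDC2 minus SPM and 0 in each other comparison.

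A block on the replicate number raised genes changed to 1615 in P-IV.I minus P-IV.II, 193 in P-IV.II minus SPM and 143 in P-IV.I minus PcDC2, the interaction to 209 and the genes higher in P-IV.II to 18. The labels do not say whether equal numbers share an animal or a sort. The replicate deviations of equal numbers correlated between SPM and P-IV.II (r = 0.71), SPM and P-IV.I (0.55) and P-IV.II and P-IV.I (0.34), but not with PcDC2 (0.04, 0.05 and -0.28). Shared sets for these 3 groups therefore stay open, and the counts without the block are the lower ones.

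When 1 library of a replicated group was left out, the lone library remaining was assumed to vary like the other groups. This also lowers the residual degrees of freedom. Comparisons that do not include that group can therefore change their count of calls at unchanged log2 fold changes. Lowest and highest counts were 366 and 1010 for P-IV.I minus P-IV.II, 24 and 63 for P-IV.II minus SPM, 15 and 54 for P-IV.I minus PcDC2, 1089 and 2035 for PcDC2 minus SPM, 554 and 1123 for P-IV.I minus SPM, 924 and 2213 for P-IV.II minus PcDC2, 29 and 76 for the interaction, 0 and 3 for genes higher in P-IV.I and 0 and 4 for genes higher in P-IV.II. Gene lists changed were 13 and 17, 14 and 18, 17 and 21, 15 and 17, 15 and 18, and 14 and 17 in the same order of comparisons. Positions ran from 0.668 to 0.743 for P-IV.I and 0.131 to 0.255 for P-IV.II, the shared direction from 99.4% to 99.8% and Pearson's r from 0.624 to 0.802. Without PcDC1 the counts were 1010, 124, 75, 2075, 1152 and 2181 in that order, and 117 for the interaction.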

Other observations

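Most members of the T and natural killer cell list differed between PcDC2 and the macrophage groups, but not as 1 unit. In PcDC2 minus SPM 8 were higher, 1 lower and 0 not passing of 9 (8 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0079, and adjusted p = 0.315 with an estimated correlation), and 1 to 8 were higher when 1 library was left out. Cd4 was among the higher ones at 2.99 ± 0.33 (adjusted p = 0.00048), and the lower one was Cd2 at -3.40 ± 0.26 (adjusted p = 9.8e-05). In P-IV.II minus PcDC2 7 were lower, 1 higher and 1 not passing (8 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0155, and adjusted p = 0.438 with an estimated correlation), and 2 to 7 were lower when 1 library was left out. In P-IV.I minus PcDC2 0 of 9 were called, but 6 were lower and 1 higher adjusted over the list alone (camera adjusted p = 9.2e-06, and adjusted p = 0.125 with an estimated correlation). In P-IV.I minus P-IV.II 1 was higher, 1 lower and 7 not passing (camera adjusted p = 0.82, and adjusted p = 0.90 with an estimated correlation). The summed FPKM of the list was 110 to 140 in SPM, 171 to 215 in P-IV.II, 38.9 to 49.3 in P-IV.I and 46.0 to 55.7 in PcDC2. Cd2 made up most of it in SPM (130 and 103 FPKM) and P-IV.II (163 and 207), but not in PcDC2 (8.68 and 11.6). Whether the other members come from lymphocytes in the sorts was not tested.

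Oxidative phosphorylation genes were called lower as a list in P-IV.I than in P-IV.II (camera adjusted p = 1.7e-07, and adjusted p = 0.452 with an estimated correlation), with 1 lower, 0 higher and 30 not passing of 31 by limma and 0 adjusted over the list alone. After median-ratio rescaling 3 were lower, and 0 to 2 were lower when 1 library was left out. At the preset correlation the oxidative phosphorylation list was also called higher in P-IV.II than in SPM (camera adjusted p = 3.2e-07) and than in PcDC2 (2.9e-06). No call remained with an estimated correlation. It was not called in PcDC2 minus SPM (camera adjusted p = 0.0892), P-IV.I minus SPM (0.0825) or P-IV.I minus PcDC2 (0.628). The correlation with transcript length was also strongest in comparisons with P-IV.II, and the part of length here was not tested. Lysosome genes were called lower in P-IV.I than in P-IV.II too (camera adjusted p = 0.00014, and adjusted p = 0.174 with an estimated correlation). Of 29 lysosome genes 2 were lower, 2 higher and 25 not passing, with 3 lower and 2 higher adjusted over the list alone. After median-ratio rescaling 5 lysosome genes were lower and 2 higher, and when 1 library was left out 1 to 2 were lower and 0 to 2 higher. Among them Ctsd, a lysosomal protease, changed by -3.07 in P-IV.I minus P-IV.II.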
